A study of Arabidopsis thaliana with 24 samples.

How the data were processed

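Whole rosettes of 3-week-old Arabidopsis thaliana plants of 4 lines, exposed to ozone or not, were sequenced as 24 libraries in 8 groups of 3. Per the labels, 3 biological replicates of pooled rosettes were prepared for each group with a TruSeq RNA v2 kit. Per the submitters' processing notes, reads were handled with FastQC, Bowtie2, SAMtools and HTSeq on the TAIR10 build. Their versions, order and strand setting are not stated. The deposited values are counts of reads per annotated locus in 1 table per library. All values were whole numbers and the totals ranged from 13633768 to 25789925 counts per library. All 279 loci of the organelle genomes had 0 counts in every library and AOP2 is not among the loci, so neither was analysed. Of 32678 loci, 31912 were found in the reference annotation, which supplied symbols and positions only. Transposable element genes cannot be told from other pseudogenes there, and no pseudogene was named.

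Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9 and numpy 2.4.6. Genes were kept by filterByExpr on the groups (minimum count 10, minimum total count 15), scaled by TMM factors and fitted with the robust quasi-likelihood model of edgeR over all 24 libraries with 1 mean per group. Each comparison was a 2-sided contrast of group means, or of differences of means for the response differences, with Benjamini-Hochberg adjustment over the 20554 genes tested, and a gene was called at an adjusted p under 0.05. Levels are CPM scaled by the TMM factors and log2 fold changes carry the standard error of the fit. Where all libraries of a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts in a group, the ratio of CPM is given with its 95% Poisson interval, and no fitted fold change is given. These bounds and intervals cover counting error only.

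The 22 gene lists were tested with limma camera on log2 CPM (prior count 2) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Alternatives were an estimated correlation, fry and the replicate block. Called members were also counted after adjustment over the list alone. The lists cover hormones, guard cells, oxidative stress, immunity, kinases, metabolism, photosynthesis, heat shock, senescence, the clock and flowering, with root and flower markers for other organs. Genes were named by a rule fixed in advance. It takes the 6 called genes with the largest change in each direction among those with a mean log2 CPM of at least 1 and the same direction in all library pairs, or groups that do not overlap for control differences. It adds the list members with the smallest adjusted p and those against their list's direction. PR1, ICS1, PR2, PR5, WRKY70, RBOHD, SLAC1, ZAT12 and FLC are always named. Of 907 called genes that the rule gave, 284 are printed. Among list members these were chosen after the values were seen, with preference for calls that held in all alternatives, so the printed genes are more stable than the rest. The result of 1 gene that the rule gave is not reported.

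Shared calls of 2 lines were set against the number expected of independent lists. The sets of genes called in Col-0 were tested between controls of the other lines by camera and by an exact permutation test of the mean score per library. The position test counted neighbouring called genes against 10000 permutations of the calls. Genes with an absolute log2 difference of at least 2 between Te and C24 controls were scored for which of these CT101 was nearer to.

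Methods were tested on simulated negative binomial counts of independent genes, with C24 control means, real library sizes and estimated spread. Only 50 genes changed by each fold. The ozone test recovered 24%, 56%, 92% and 96% at 1.5, 2, 4 and 8-fold (2 unchanged genes called). The control test recovered 30%, 78%, 98% and 92% (6 unchanged genes called) and the response test 4%, 52%, 88% and 88% (5 called). Camera called the 1 moved list of 30 genes and 0 of 21 unmoved, not a test of its preset correlation. The position test gave a ratio of 3.36 for simulated calls in runs and 1.06 for random calls.

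Pairing by replicate number was checked by correlating residuals of equally numbered libraries. Of 12 group pairs of equal treatment, 11 passed a minimum of 0.1 (median 0.356). Numbers were taken to pair libraries of equal treatment across lines, except CT101 and Col-0 controls (lowest 0.0186), though the main fit omits this pairing. In the ozone comparisons they passed for C24 (lowest 0.103) and CT101 (0.162), not for Te (0.04) or Col-0 (0.049). Alternatives were RLE factors, no filter, DESeq2 1.42.0, a replicate block, a fit of the compared libraries alone, omission of organelle loci, omission of each library in turn, a block within each treatment, library totals alone and 1 gene per 100 kb in the position test.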

Results

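RNA from whole rosettes of 3-week-old Arabidopsis thaliana plants was sequenced in 24 libraries, each made from a pool of rosettes. The plants belonged to 4 lines: the accessions C24 and Te, which the series describes as unlike in their sensitivity to ozone, the reference accession Col-0, and CT101, a line whose origin the labels do not give. Each line was either exposed to 350 ppb ozone for 2 h or kept as a control, which made 8 groups of 3 biological replicates. The interval between exposure and sampling is not stated. Means of the deposited counts per library, in 1e6, were 17.2, 19.8, 20.6 and 19.5 in C24, Te, CT101 and Col-0 controls and 18, 16.9, 18.1 and 22.2 under ozone. At the median depth a single count equals 0.0532 count per 1e6 (CPM). Of 32678 loci, 5106 had no count in any library and 20554 passed the filter on low counts and were tested. The first principal component held 58.1% of the variance and separated ozone from control libraries in every line, while the components after it, with 14% and 13.5%, separated the lines. Ozone replicate 2 lay lowest of the ozone libraries on the first component in every line, at 41.4, 86.4, 96.5 and 62.8 in C24, Te, CT101 and Col-0, where the next replicate lay at 95.1, 97, 114 and 89.9. The 10 most abundant genes took 9.41% to 11.4% of the counts in the means of the control groups and 5.52% to 6.77% under ozone.

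**Figure D1:**
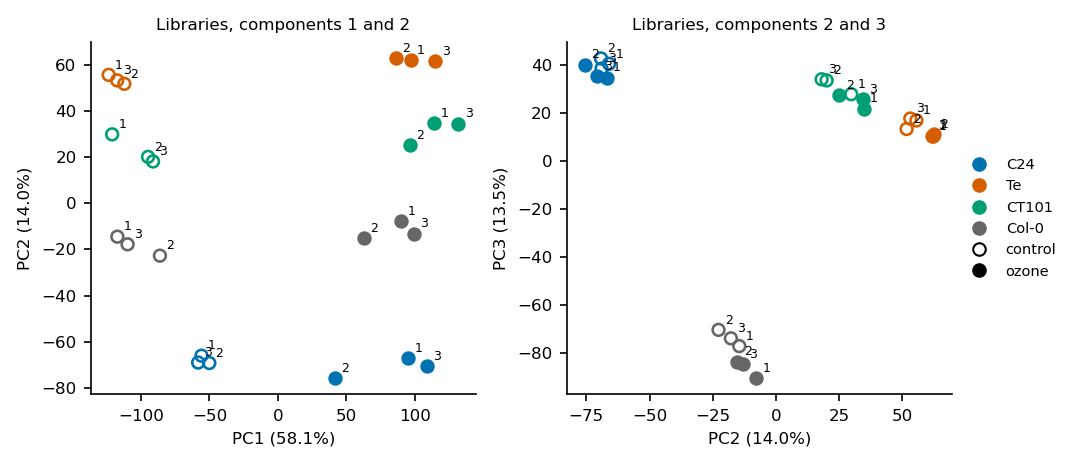
Principal components of log2 CPM in the 24 libraries, with components 1 and 2 on one panel and 2 and 3 on the other, the percentage of variance on each axis, and 1 point per library coloured by line (open, control; filled, ozone). All control libraries lie below 0 on component 1 and all ozone libraries above 0, lowest in replicate 2 of each line.

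The first comparison asked which genes ozone changed in C24. ZAT12 (AT5G59820), a zinc finger regulator of responses to reactive oxygen, rose from 5.64 ± 2.1 CPM in the controls to 142 ± 77.5 CPM under ozone (mean ± SD, n = 3), a log2 fold change of 4.65 ± 0.48 (SE) with an adjusted p of 3.2e-07. ICS1 (AT1G74710), the isochorismate synthase of salicylic acid synthesis, rose from 65.5 ± 2.32 to 835 ± 406 CPM (log2 fold change 3.67 ± 0.35, adjusted p = 1.5e-07). PROPEP3 (AT5G64905), the precursor of an immune signalling peptide, went from 0.32 ± 0.141 to 47.5 ± 29.3 CPM (log2 fold change 7.19 ± 0.78, adjusted p = 5.3e-07). RBOHD, the NADPH oxidase that makes apoplastic superoxide, rose by 2.17 ± 0.20 (log2), WRKY70, a transcription factor of salicylic acid signalling, by 1.61 ± 0.26, and PR5, a pathogenesis-related protein, by 2.08 ± 0.52. PR1 (-0.03, adjusted p = 0.99), SLAC1, the anion channel of guard cells (-0.06, adjusted p = 0.84), FLC, a repressor of flowering (-0.22, adjusted p = 0.15), and PR2 (1.81 ± 0.74, adjusted p = 0.051) did not pass. PR2 passed with RLE factors (0.0499), in DESeq2 (0.04), with the replicate block (0.026) and in a separate fit (0.0013) (range 0.0013 to 0.13). FLC passed in DESeq2 (0.037) and with library totals alone (0.039) (range 0.037 to 0.37). Ranges beside such values hold the adjusted p over all alternatives, and a separate fit holds the compared libraries alone. Among the other large increases, the phloem protein gene PP2-B7 rose by 7.47 ± 0.69 and AT5G64790, a glycosyl hydrolase gene, by 7.06 ± 0.70, while the ozone to control ratio of CPM was 390.4 (95% interval 70.1 to 15419) for AT4G18540 and 282 (95% interval 78 to 2328) for AT4G04480, each with 1 to 3 control counts. The largest decreases included AT5G66580 (-3.31 ± 0.57) and the small auxin-up RNA genes AT1G29450 (-3.13), AT5G18030 (-3.11), SAUR20 (-2.96) and SAUR24 (-2.95), clustered paralogs whose shared reads were not measured. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, used throughout, 9825 of 20554 genes passed the test, 5259 higher and 4566 lower under ozone, 2755 and 1001 of them by at least 2-fold. Library totals alone gave 4526 higher and 5625 lower.

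In Te, ozone raised ZAT12 from 1.56 ± 0.606 to 245 ± 83.7 CPM (SD, n = 3; log2 fold change 7.28 ± 0.55 with SE) and ICS1 from 24.2 ± 1.59 to 809.6 ± 228 CPM (5.06 ± 0.38). AACT1 (AT5G61160), annotated as an anthocyanin acyltransferase, rose from 0.185 ± 0.207 to 244 ± 81.5 CPM (10.31 ± 0.62). PR5 (3.98 ± 0.56), RBOHD (2.88 ± 0.21), PR2 (2.85 ± 0.78) and WRKY70 (2.69 ± 0.27) rose as well, with adjusted p from 5.3e-10 for RBOHD to 0.0034 for PR2. PR1 (1.1 ± 1.23, adjusted p = 0.45), FLC (-0.03) and SLAC1 (-0.21) did not pass. AT1G71520, annotated as a DNA-binding protein, had no count in the Te controls and 32.6 ± 10.5 CPM under ozone, at least 631-fold higher against a floor of 3 counts over the group. By the same floor AT3G44830 was at least 394-fold higher and AT1G76470 at least 279-fold. The small auxin-up RNA genes AT5G18030 (-5.09 ± 0.64), SAUR29 (-5.00) and SAUR20 (-4.95) fell, and AT5G66580 had a control to ozone ratio of 82 (95% interval 28.1 to 398). With ozone, 12929 genes passed the test, 6578 higher and 6351 lower under ozone, 4090 and 2385 of them by at least 2-fold. Library totals alone gave 5812 higher and 7444 lower.

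The same question in CT101 gave increases of 6.65 ± 0.53 (log2 fold change ± SE) for ZAT12, 4.68 ± 0.37 for ICS1, 2.84 ± 0.27 for WRKY70, 2.65 ± 0.21 for RBOHD and 2.29 ± 0.52 for PR5, from 3 ozone and 3 control libraries. ICS1 went from 32 ± 5.43 to 822 ± 219.7 CPM (SD, n = 3). PR2 rose by 2.00 ± 0.75 (adjusted p = 0.024). PR2 failed without CT101 control replicate 1 (0.094), CT101 ozone replicate 2 (0.051) or 3 (0.063) (range 0.0085 to 0.094). PR1 (0.30, or -1.06 without CT101 ozone replicate 2), SLAC1 (0.03) and FLC (-0.17) did not pass, with adjusted p of 0.85, 0.91 and 0.24. AT1G56060, a small cysteine-rich membrane protein gene, rose from 0.483 ± 0.303 to 496 ± 221 CPM (10.01 ± 0.80). The ozone to control ratio was 1418 (95% interval 393 to 11709.7) for the cytochrome P450 gene CYP82C3 and 1212 (95% interval 218 to 47866) for AT1G71520. Among genes with no control count were AT4G37710, a VQ motif gene (at least 290.5-fold higher) and AT2G23270 (at least 137-fold). PRE1, a helix-loop-helix regulator of cell elongation, changed by -4.50 ± 0.49, and AT5G18030 (-5.12), SAUR20 (-4.99) and AT5G66580 (-4.75) were other large decreases. By count, 13424 genes passed the test, 6772 higher and 6652 lower under ozone, 4206 and 2857 of them by at least 2-fold. Library totals alone gave 6197 higher and 7300 lower.

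Col-0, the accession whose genome served as the reference, answered the question of what ozone changed with ZAT12 (6.69 ± 0.54, log2 fold change ± SE), ICS1 (3.17 ± 0.35), RBOHD (2.78 ± 0.21) and WRKY70 (1.91 ± 0.26) among the genes that rose. ICS1 stood at 29.3 ± 15.2 CPM in the controls and 264 ± 40.6 CPM under ozone (SD, n = 3). PR5 rose by 1.57 ± 0.51 (adjusted p = 0.013). PR5 failed without Col-0 control replicate 1 (0.065) or 3 (0.064), in a separate fit (0.083) (range 2.6e-04 to 0.083). PR2 (1.72 ± 0.74, adjusted p = 0.056), FLC (0.35), SLAC1 (0.19) and PR1 (-0.64) did not pass. Without Col-0 control replicate 2 the log2 fold changes of PR5, PR2 and PR1 were 2.56, 3.46 and 0.65. PR1 was lowest in replicate 1 of all 8 groups, with 0.0986 CPM in Col-0 ozone replicate 1 against 87.0 and 106 CPM in the others. PR2 passed in DESeq2 (0.048), with the replicate block (0.031), without Col-0 control replicate 2 (6.7e-04) and without Col-0 ozone replicate 1 (0.022) (range 6.7e-04 to 0.28). AACT1 rose from 0.124 ± 0.0772 to 348 ± 89.2 CPM (11.31 ± 0.65) and DIN11, an oxygenase gene induced in darkness, from 0.400 ± 0.296 to 289.9 ± 45.7 CPM (9.40 ± 0.90). Ratios of ozone to control were 2330.4 (95% interval 418 to 92048) for the oxidoreductase gene AT1G59950 and 1494 (95% interval 414 to 12338) for CYP82C3, while PROPEP2, another immune peptide precursor, had no control count and was at least 86.8-fold higher. EXPA8, a cell wall expansin, fell from 104 ± 55 to 4.88 ± 2.29 CPM (-4.40 ± 0.60), and BAS1, a cytochrome P450 that inactivates brassinosteroids (-4.15), AT1G29450 (-4.52) and SAUR20 (-4.07) fell by similar amounts. Across the genome, 11696 genes passed the test, 6169 higher and 5527 lower under ozone, 3526 and 1731 of them by at least 2-fold. Library totals alone gave 5345 higher and 6700 lower. With these the median log2 fold change of all genes moved by -0.11 in C24, -0.14 in Te, -0.10 in CT101 and -0.13 in Col-0, and the majority of calls turned from higher to lower in each line. All changes given here are relative to the scaled libraries.

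**Figure D2:**
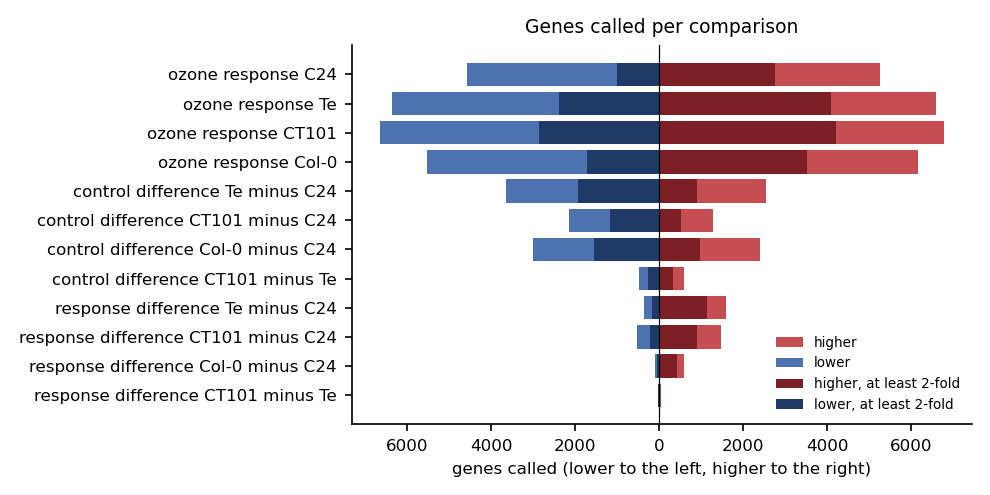
Number of genes that passed the test in each of the 12 comparisons, lower to the left and higher to the right of 0, with darker bars for changes of at least 2-fold. The ozone responses hold 9825 to 13424 genes and the difference in response between CT101 and Te 66.

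**Figure D3:**
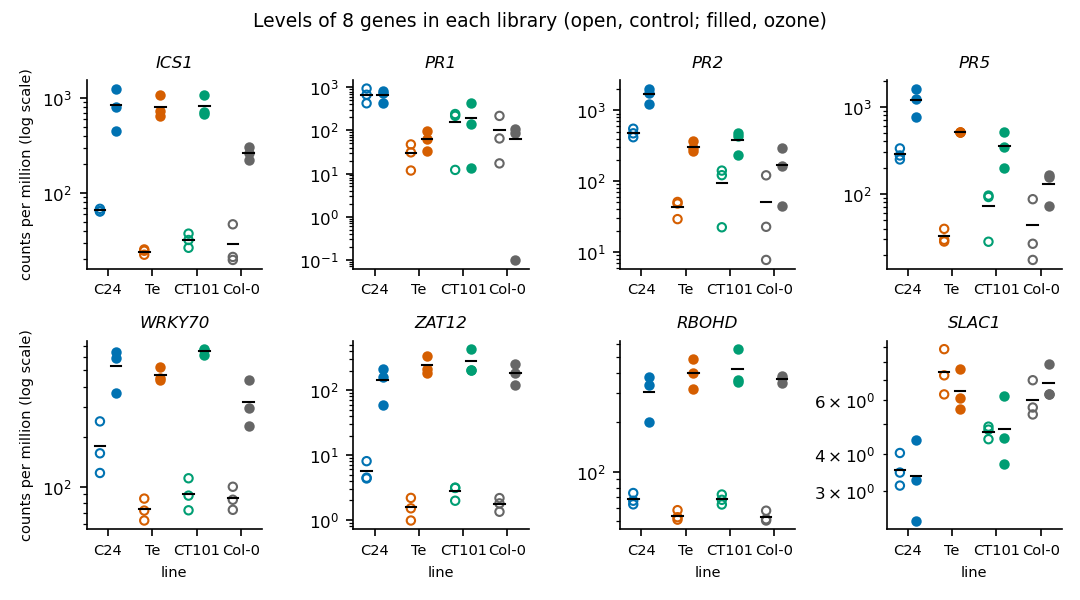
Levels of 8 genes in each library in CPM on a log axis, by line, with open points for control and filled points for ozone libraries (n = 3 per group). ZAT12 lies between 1.56 and 5.64 CPM on average in the Te and C24 controls and at 245 and 142 CPM under ozone.

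Gene lists fixed before the data were examined were tested against all other genes with camera at a preset correlation. Values of lists under ozone run in the order C24, Te, CT101, Col-0. Of 30 measured genes of salicylic acid synthesis and signalling, 22, 23, 24 and 22 rose and 1, 2, 2 and 0 fell. Medians were (log2) 1.85, 3.20, 3.01 and 2.05. The salicylic acid list passed camera in every line (adjusted p = 1.6e-06, 1.2e-07, 9.2e-07 and 5.0e-06), with 23 and 1, 24 and 2, 24 and 2 and 23 and 1 adjusted over the list alone (below, within the list). Camera gave adjusted p = 0.38, 0.3, 0.3 and 0.32 with an estimated correlation. PBS3, which makes the salicylic acid precursor isochorismoyl glutamate, rose by 3.57 (log2) and NPR3, a salicylic acid receptor, by 2.13 in C24. CBP60G, a transcription factor of ICS1, rose by 5.94 in Te and 4.07 in Col-0, WRKY46 by 5.83 in CT101, and PAD4, a partner of EDS1 in immunity, by 3.63 in Te. Against the direction of the list, ACD6 fell in Te (-1.34) and CT101 (-1.59) and PCC1 in CT101 (-1.37, or -2.08 without CT101 ozone replicate 2). Of 18 measured WRKY transcription factors of stress, 17, 18, 17 and 18 rose and 0, 0, 0 and 0 fell. Median log2 changes were 3.33, 5.04, 4.83 and 4.64. The WRKY list passed camera in every line (adjusted p = 3.2e-11, 7.6e-10, 3.4e-09 and 2.3e-10), with 17 and 0, 18 and 0, 18 and 0 and 18 and 0 within the list. This became adjusted p = 0.15, 0.16, 0.2 and 0.14 by estimated correlation. WRKY40 rose by 6.33 in C24, 8.62 in Te, 8.06 in CT101 and 6.71 in Col-0. Of 14 measured genes of pattern-triggered immunity and MAP kinases, 13, 13, 13 and 14 rose and 0, 0, 0 and 0 fell. Their medians were (log2) 2.61, 3.65, 3.44 and 2.96. The immunity list passed camera in every line (adjusted p = 6.9e-09, 8.5e-08, 2.2e-07 and 3.3e-08), with the same counts within the list. It had adjusted p = 0.083, 0.14, 0.16 and 0.11 by estimated correlation. Among them the ubiquitin ligase gene PUB23 rose by 4.31 in C24, 5.69 in Te and 6.04 in CT101, and the cytochrome P450 gene CYP81F2 by 5.76 in Col-0. Of 31 measured cysteine-rich receptor-like kinases, 26, 28, 29 and 26 rose and 1, 2, 2 and 2 fell. The medians (log2) were 1.98, 3.37, 2.92 and 2.32. The receptor-like kinase list passed camera in every line (adjusted p = 1.1e-09, 2.4e-09, 2.3e-08 and 5.9e-09), with 27 and 2, 28 and 2, 29 and 2 and 28 and 2 within the list. Camera gave adjusted p = 0.15, 0.16, 0.22 and 0.14 by estimated correlation. CRK11 rose by 4.74, 6.5, 5.86 and 5.75, whereas CRK42 fell (-1.38, -2.03, -2.75 and -2.00, with -2.11 in C24 without C24 ozone replicate 2). Several of these stand in tandem, and shared reads were not measured. WRKY40, WRKY53, CRK42, EDS5 and CHS overlap loci on the other strand and are uncertain, as the strand setting is not stated. Of all 123 list calls in the 12 comparisons, 3 held by estimated correlation, those of ethylene in ozone-treated C24, Te and Col-0.

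Hormone genes other than those of salicylic acid followed. Of 23 measured genes of ethylene synthesis and signalling, 22, 22, 21 and 22 rose and 0, 0, 0 and 0 fell. Medians were (log2) 2.40, 3.06, 3.07 and 2.66. The ethylene list passed camera in every line (adjusted p = 9.6e-12, 1.2e-09, 6.2e-09 and 5.9e-10), with the same counts within the list. This became adjusted p = 0.018, 0.047, 0.068 and 0.041 by estimated correlation. ACO4, an oxidase that makes ethylene, rose by 3.19 in C24, 4.58 in Te, 4.66 in CT101 and 3.77 in Col-0, and the transcription factor genes ERF1 by 5.55 in C24 and ORA59 by 6.41 in Col-0. Of 30 measured genes of jasmonate synthesis and signalling, 15, 19, 16 and 21 rose and 7, 4, 4 and 2 fell. Median log2 changes were 0.36, 1.69, 1.59 and 2.17. The jasmonate list passed camera in Te, CT101 and Col-0 (adjusted p = 0.16, 0.001, 0.012 and 5.9e-06), with 15 and 8, 19 and 4, 16 and 4 and 21 and 2 within the list. It had adjusted p = 0.68, 0.35, 0.51 and 0.25 by estimated correlation. The repressor gene JAZ1 (3.97 in C24, 5.77 in Te), the lipoxygenase gene LOX4 (3.8 in C24, 5.93 in Te, 5.24 in Col-0) and the allene oxide cyclase gene AOC3 (3.40 in C24, 5.61 in Te, 6.03 in CT101) rose. AOC4 fell in each line (-0.55, -0.74, -0.87 and -0.55), and the storage protein gene VSP1 fell in C24 (-3.08). Of 16 measured genes of auxin response and cell expansion, 1, 0, 2 and 0 rose and 7, 11, 10 and 12 fell. Their medians were (log2) -0.80, -1.81, -1.52 and -1.96. The auxin list passed camera in Te, CT101 and Col-0 (adjusted p = 0.063, 5.8e-04, 0.019 and 2.5e-05), with 2 and 7, 0 and 11, 2 and 10 and 0 and 13 within the list. Camera gave adjusted p = 0.52, 0.21, 0.32 and 0.14 by estimated correlation. With the replicate block the auxin list in C24 had an adjusted p of 0.041. The auxin repressor gene IAA6 (-2.11) and the auxin carrier gene PIN3 (-1.11) fell in C24, IAA1 (-3.07) and SAUR15 (-3.13) in Te, IAA5 (-3.39) in CT101 and EXPA8 in Col-0, while GH3.5 rose in C24 (0.85) and IAA2 in CT101 (1.07). Of 16 measured genes of abscisic acid response, 3, 5, 4 and 4 rose and 3, 6, 6 and 2 fell. The medians (log2) were -0.19, -0.36, -0.71 and -0.26. Of 22 measured guard cell genes, 6, 5, 6 and 9 rose and 4, 6, 5 and 4 fell. Medians were (log2) -0.01, 0.10, 0.07 and 0.11. Neither list passed in any line, with adjusted p of 0.9, 0.83, 0.57 and 0.91 for abscisic acid and 0.9, 0.98, 0.81 and 0.52 for guard cells. CPK6, a kinase that activates guard cell channels, rose in C24 (1.65) and Te (3.35), and GHR1, a receptor-like protein needed for stomatal closure, fell in C24 (-0.84), Te (-1.26), CT101 (-1.29) and Col-0 (-1.19). Mean and median differed in sign for abscisic acid in C24 and Col-0 and for guard cells in C24, and the guard cell test in Te pointed down while its median was 0.10.

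Lists tied to reactive oxygen and detoxification were tested next. Of 15 measured oxidative stress markers, 14, 15, 15 and 14 rose and 0, 0, 0 and 0 fell. Median log2 changes were 3.33, 6.11, 5.25 and 4.80. The oxidative stress list passed camera in every line (adjusted p = 6.9e-09, 2.4e-09, 1.6e-08 and 1.1e-08), with the same counts within the list. This became adjusted p = 0.15, 0.16, 0.2 and 0.14 by estimated correlation. ZAT10, a zinc finger gene, rose by 3.90 in C24 and 6.34 in Te, ZAT6 by 5.35 in Col-0, and NUDT7, a Nudix hydrolase gene, by 5.39 in Te and 5.04 in CT101. Of 12 measured glutathione S-transferase genes, 12, 12, 12 and 12 rose and 0, 0, 0 and 0 fell. Their medians were (log2) 3.86, 4.29, 5.08 and 3.97. The transferase list passed camera in every line (adjusted p = 1.0e-06, 5.3e-06, 2.3e-06 and 5.5e-06), with the same counts within the list. It had adjusted p = 0.19, 0.21, 0.22 and 0.21 by estimated correlation. GSTF6 rose by 4.24 in C24, GSTU24 by 8.65 in Te and 8.27 in CT101, and GSTU4 by 7.09 in Col-0, in families with tandem copies. Of 14 measured genes of reactive oxygen scavenging, 4, 7, 6 and 7 rose and 2, 3, 4 and 3 fell. The medians (log2) were 0.04, 0.11, 0.14 and 0.34. The scavenging list did not pass in any line (adjusted p = 0.96, 0.63, 0.63 and 0.25), although GSH2, the glutathione synthetase gene, rose in Te (2.51) and Col-0 (2.97) and the catalase gene CAT2 fell in Te (-1.29), CT101 (-2.02) and Col-0 (-1.24). Of 12 measured heat shock protein genes, 10, 10, 10 and 10 rose and 0, 0, 0 and 0 fell. Medians were (log2) 3.67, 3.65, 4.67 and 2.73. The heat shock list passed camera in every line (adjusted p = 1.6e-06, 2.6e-04, 1.3e-04 and 3.7e-04), with 11 and 0, 11 and 0, 10 and 0 and 10 and 0 within the list. Camera gave adjusted p = 0.21, 0.31, 0.3 and 0.31 by estimated correlation. HSP90.1 rose by 5.49 in C24 and 6.11 in Col-0, HSP17.6A by 7.54 in Te and HSP23.5 by 7.32 in CT101.

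Metabolic lists came after these. Of 11 measured genes of tryptophan and camalexin synthesis, 9, 9, 9 and 9 rose and 0, 0, 0 and 0 fell. Median log2 changes were 2.19, 2.88, 2.58 and 2.58. The tryptophan list passed camera in every line (adjusted p = 1.2e-05, 2.5e-05, 4.9e-04 and 9.2e-05), with the same counts within the list. This became adjusted p = 0.21, 0.21, 0.3 and 0.25 by estimated correlation. CYP71A12, a cytochrome P450 gene of camalexin and indole carbonyl nitrile synthesis that shares sequence with its neighbour CYP71A13, rose by 5.58, 9.05, 8.60 and 9.06. Of 13 measured genes of aliphatic glucosinolate synthesis, 0, 0, 0 and 0 rose and 12, 11, 13 and 13 fell. Their medians were (log2) -0.82, -0.82, -1.21 and -0.99. The glucosinolate list passed camera in every line (adjusted p = 3.3e-06, 6.0e-04, 2.4e-05 and 5.5e-06), with 0 and 13, 0 and 12, 0 and 13 and 0 and 13 within the list. It had adjusted p = 0.25, 0.35, 0.3 and 0.25 by estimated correlation. The regulator gene MYB28 fell in C24 (-1.08), Te (-1.48) and CT101 (-1.81), and MYB29 in Col-0 (-1.66). Of 32 measured genes of photosynthesis and chlorophyll synthesis, 0, 0, 0 and 0 rose and 23, 32, 32 and 31 fell. The medians (log2) were -0.52, -0.83, -1.23 and -0.66. The photosynthesis list passed camera in every line (adjusted p = 1.0e-06, 8.5e-08, 3.5e-10 and 2.4e-07), with 0 and 28, 0 and 32, 0 and 32 and 0 and 32 within the list. Camera gave adjusted p = 0.52, 0.35, 0.3 and 0.38 by estimated correlation. PORC, a chlorophyll synthesis gene, fell in C24 (-0.78), Te (-1.01) and CT101 (-1.48), and HEMA1, at the start of that pathway, in Te (-1.29) and Col-0 (-1.26). Of 14 measured phenylpropanoid and flavonoid genes, 4, 5, 5 and 5 rose and 4, 6, 7 and 6 fell. Medians were (log2) -0.73, -0.33, -0.85 and -0.59. This list did not pass in any line (adjusted p = 0.34, 0.83, 0.54 and 0.53), its mean and median differed in sign in Te, and its members went both ways. PAL2, at the entry of the phenylpropanoid pathway, rose in C24 (1.36), Te (3.56), CT101 (3.66) and Col-0 (2.52), and the flavonoid gene CHS fell in C24 (-1.19) and Te (-1.56) and FLS1 in CT101 (-2.45).

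**Figure D4:**
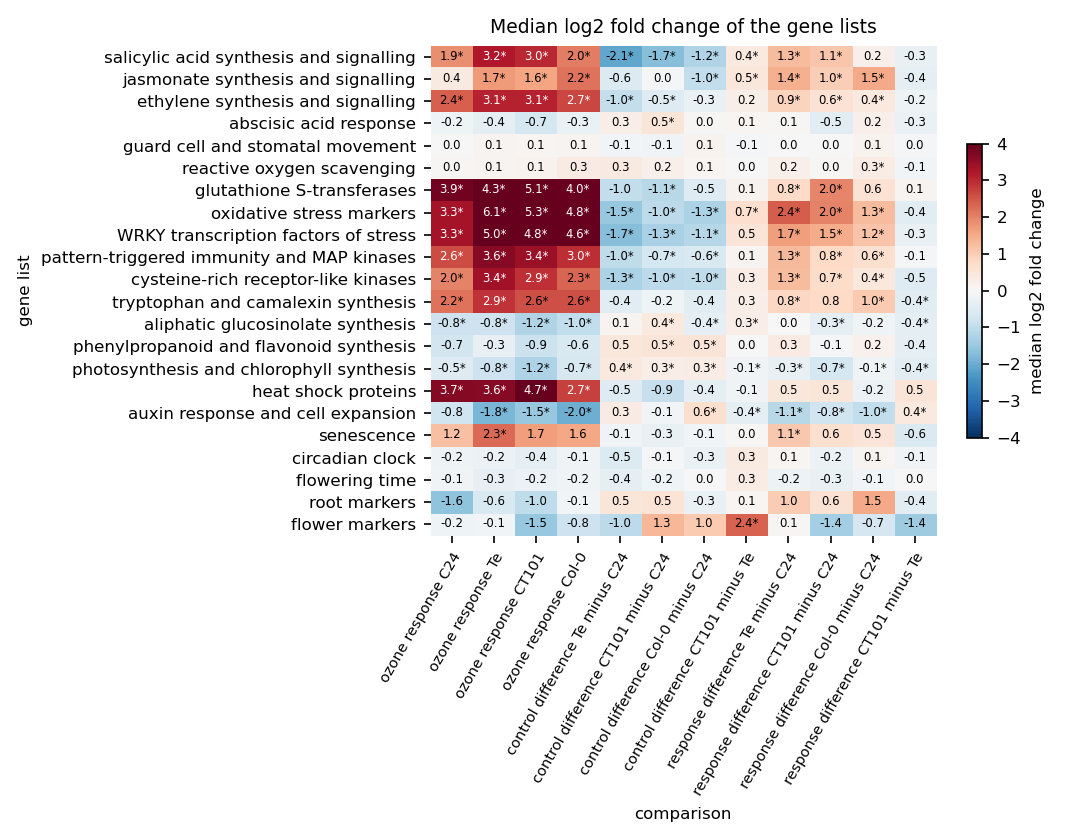
Median log2 fold change of the 22 gene lists in the 12 comparisons (columns), red for higher and blue for lower, with a mark where the list passed camera. Medians of the oxidative stress list under ozone run from 3.33 in C24 to 6.11 in Te.

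Whether the lines responded with the same genes was asked by counting shared calls, since the ozone responses of different lines have no library in common. In all 4 lines 4445 genes rose and 3644 fell, 2313 of them rising and 714 falling by at least 2-fold in every line, out of 15707 that changed in at least 1 line, and 123 rose in some lines and fell in others. C24 and Te shared 4816 genes that rose and 4067 that fell, where independent lists would share 1683 and 1411, and 39 genes went opposite ways. For Te and CT101 the shared genes numbered 6014 and 5653, against 2167 and 2055, with 17 in opposition. Over the 8089 genes that changed the same way in all lines, the median absolute log2 fold change was 0.823 in C24, 1.27 in Te, 1.35 in CT101 and 1.06 in Col-0.

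Control plants of Te and C24 were compared to ask how these accessions differ without ozone. Genes of salicylic acid signalling were lower in Te, among them AED1, an extracellular protease gene (-5.39 ± 0.62, log2 fold change ± SE), PR2 (-3.50 ± 0.80), PR5 (-3.13 ± 0.54), CBP60G (-2.96), PAD4 (-1.78), ICS1 (-1.44 ± 0.33) and WRKY70 (-1.26 ± 0.26). PR1 averaged 30 ± 17.8 CPM in Te and 679 ± 255 CPM in C24 (SD, n = 3; -4.50 ± 1.39, adjusted p = 0.018), and ZAT12 differed by -1.85 ± 0.51 (adjusted p = 0.0094). PR1 failed without Te control replicate 1 (0.076) or 3 (0.061) (range 0.0015 to 0.076). ZAT12 failed without C24 control replicate 2 (0.057) (range 3.7e-04 to 0.057). SLAC1 (1.08 ± 0.21), whose locus overlaps AT1G12470 on the other strand, and FLC (0.56 ± 0.12) were higher in Te, and RBOHD (-0.33, adjusted p = 0.22) did not pass. RBOHD passed in a separate fit (0.036) (range 0.036 to 0.44). Lists lower in Te were salicylic acid (28 of 30 lower, median -2.09, adjusted p = 1.0e-09), receptor-like kinases (23 of 31 lower, median -1.26, adjusted p = 2.5e-08), WRKY factors (14 of 18 lower, median -1.71, adjusted p = 2.4e-05), immunity (9 of 14 lower, median -1.01, adjusted p = 9.4e-04), oxidative stress (8 of 15 lower, median -1.52, adjusted p = 0.0013) and ethylene (10 of 23 lower, median -0.95, adjusted p = 0.0038). The counts were 30, 24, 14, 10, 9 and 11 within the list, and these had adjusted p = 0.47 to 0.56 by estimated correlation. CRK4 (-8.73), CRK23 (-3.87), WRKY53 (-3.12), the kinase gene FRK1 (-4.03), ZAT10 (-2.64) and ERF104 (-2.40) were among them. Higher in Te was the list of photosynthesis (11 of 32 higher, median 0.40, adjusted p = 1.0e-05), with LHCA3 at 1.07. The count within the list was 14, and the list had adjusted p = 0.65 by estimated correlation. Phenylpropanoid and auxin genes did not pass (adjusted p = 0.058 each), and with the replicate block they had adjusted p of 0.00996 and 0.0396.

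The largest differences between Te and C24 controls were genes near 0 in either accession, and since reads of every line were aligned to the Col-0 genome, low expression and altered sequence look alike in them. CSA1 (AT5G17880), a TIR-type disease resistance gene, averaged 0.0673 ± 0.0781 CPM in Te and 102 ± 3.42 CPM in C24 (log2 fold change -10.43 ± 0.26). AT4G29200, annotated as related to beta-galactosidase, had no count in Te and 90.2 ± 12.1 CPM in C24, at least 1789-fold lower in Te. AT5G15360 was at least 605-fold lower, and the thionin gene AT1G66100 stood at 0.0845 CPM in Te and 222 ± 133 CPM in C24. In the other direction the F-box gene AT1G27540 averaged 208 ± 10.7 CPM in Te with 1 count in C24, a ratio of 11777 (95% interval 2114 to 465171), in a cluster of like genes whose shared reads were not measured. AT5G49640 was at least 319-fold higher in Te. In total 6189 genes passed, 2550 higher and 3639 lower in Te than in C24. Of these, 41.2% of calls were higher, and 24.8% with library totals alone, a setting that moved the median of all genes by -0.13.

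CT101 controls were compared with the same C24 control libraries to ask how CT101 differs from C24 without ozone. ARGAH2 (AT4G08870), an arginase gene, averaged 911 ± 434 CPM in CT101 and 0.713 ± 0.15 CPM in C24 (SD, n = 3; log2 fold change 10.31 ± 0.78). The C24 to CT101 ratio was 1210.1 (95% interval 335 to 9992) for PLC8, a phospholipase C gene, and 3271 (95% interval 587 to 129184) for AT3G61010, annotated as ferritin-like, and AT4G07965 was at least 295-fold lower in CT101. Higher in CT101 were AT1G27540 (ratio 11186 (95% interval 2008 to 441824)) and AT4G15242 (at least 302-fold). The salicylic acid genes CBP60G (-1.69), ACD6 (-1.90), PAD4 (-1.20) and PNP-A (-2.13) were lower in CT101, as were CRK4 (-8.59), CRK23 (-2.81), WRKY53 (-2.02) and PUB23 (-2.19). ICS1 (-1.03, adjusted p = 0.034), WRKY70 (-0.95, 0.013), PR2 (-2.34, 0.039) and PR5 (-1.99, 0.01) were lower too. PR1 (-2.12 ± 1.24, 0.29), ZAT12 (-1.04, 0.16), SLAC1 (0.42, 0.21), FLC (-0.19, 0.32) and RBOHD (-0.01, 0.99) did not pass. PR1 passed with the replicate block (0.04) (range 0.04 to 0.56). ZAT12 passed in a separate fit (0.048) and with a block within each treatment (0.025) (range 0.025 to 0.5). ICS1 failed without C24 control replicate 1 (0.08), 2 (0.079) or 3 (0.066), CT101 control replicate 1 (0.15) or 2 (0.086), with no filter (0.052) (range 0.002 to 0.15). WRKY70 failed without C24 control replicate 2 (0.14), CT101 control replicate 1 (0.085), in a separate fit (0.062) (range 0.0037 to 0.14). PR2 failed without C24 control replicate 1 (0.067), 2 (0.067) or 3 (0.087), CT101 control replicate 1 (0.16), 2 (0.052) or 3 (0.07), with no filter (0.078), in a separate fit (0.053) (range 0.0098 to 0.16). PR5 failed without CT101 control replicate 1 (0.061) (range 0.0016 to 0.061). WRKY70 was at -0.61 without C24 control replicate 2. In CT101 controls replicate 1, the lowest in PR1 here as in each group, had 12.1 CPM of PR1 against 218 and 240.2, 22.3 of PR2 against 141 and 121 and 28.2 of PR5 against 95.7 and 92.1. Lists lower in CT101 were salicylic acid (20 of 30 lower, median -1.70, adjusted p = 6.8e-10), receptor-like kinases (18 of 31 lower, median -1.03, adjusted p = 1.3e-08), WRKY factors (11 of 18 lower, median -1.30, adjusted p = 3.9e-05), immunity (7 of 14 lower, median -0.70, adjusted p = 4.4e-04), ethylene (5 of 23 lower, median -0.51, adjusted p = 0.0056), oxidative stress (5 of 15 lower, median -1.04, adjusted p = 0.0078) and transferases (4 of 12 lower, median -1.10, adjusted p = 0.038). The counts were 28, 24, 13, 9, 6, 6 and 6 within the list, and these had adjusted p = 0.42 to 0.54 by estimated correlation. The transferase list had an adjusted p of 0.0502 with the replicate block. Lists higher in CT101 were photosynthesis (2 of 32 higher, median 0.27, adjusted p = 8.2e-05), glucosinolates (3 of 13 higher and 1 lower, median 0.40, adjusted p = 0.0031), phenylpropanoids (2 of 14 higher, median 0.52, adjusted p = 0.0087) and abscisic acid (1 of 16 higher and 1 lower, median 0.47, adjusted p = 0.039). The counts were 1, 6, 3 and 0 within the list, and these had adjusted p = 0.42 to 0.54 by estimated correlation. Fry, which tests the members alone, did not call transferases, photosynthesis, glucosinolates and abscisic acid (adjusted p = 0.064 to 0.16). By count 3409 genes passed, 1270 higher and 2139 lower in CT101 than in C24, 2184 without CT101 control replicate 1 and 6284 with a block within each treatment. Of the calls, 37.3% were higher, and 25.6% with library totals alone.

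Col-0 and C24 controls, with those C24 libraries again, were compared to ask how the reference accession differs from C24 without ozone. FLC (AT5G10140), the repressor of flowering, averaged 0.851 ± 0.169 CPM in Col-0 and 36 ± 1.77 CPM in C24 (SD, n = 3; log2 fold change -5.39 ± 0.17, adjusted p = 9.0e-15). AT2G05642, annotated as nucleic acid-binding, had no count in Col-0 and 95.6 ± 9.47 CPM in C24, at least 1935-fold lower, the resistance gene AT5G47260 was at least 167-fold lower, and AT4G29200 had a C24 to Col-0 ratio of 5504 (95% interval 988 to 217395). AT2G15292 was at least 409-fold higher in Col-0, and AT1G25175 (at least 1421-fold) and AT1G24996 (at least 1078-fold), which overlaps AT1G25054 on the other strand, lie in a repeated region where reads cannot be assigned with certainty. AED1 (-3.03), PNP-A (-3.17), PR5 (-2.70 ± 0.53) and PR2 (-3.25 ± 0.79) were lower in Col-0, as were ICS1 (-1.16), WRKY70 (-1.04) and ZAT12 (-1.66), while SLAC1 was higher (0.76) and PR1 (-2.76 ± 1.28, adjusted p = 0.12) and RBOHD (-0.35, adjusted p = 0.21) did not pass. PR1 passed with the replicate block (0.012) and with a block within each treatment (0.025) (range 0.012 to 0.3). RBOHD passed in a separate fit (0.031) (range 0.031 to 0.43). ICS1 failed without Col-0 control replicate 1 (0.068) or 3 (0.072) (range 6.5e-04 to 0.072). WRKY70 failed without C24 control replicate 2 (0.056) (range 7.3e-04 to 0.056). ZAT12 failed without C24 control replicate 2 (0.11), Col-0 control replicate 1 (0.0505) or 3 (0.075) (range 0.0014 to 0.11). SLAC1 failed without C24 control replicate 3 (0.055), Col-0 control replicate 1 (0.062) (range 0.0014 to 0.062). PR2 failed in a separate fit (0.069) (range 1.2e-04 to 0.069). Col-0 control replicate 2 had 86.9 CPM of PR5 against 17.5 and 26.8, replicate 2 being the highest in Te and CT101 controls too, and without it PR2 was at -4.99. Lists lower in Col-0 were salicylic acid (21 of 30 lower, median -1.20, adjusted p = 3.9e-08), receptor-like kinases (18 of 31 lower and 2 higher, median -1.02, adjusted p = 6.7e-06), jasmonate (14 of 30 lower and 1 higher, median -1.0, adjusted p = 3.6e-04), WRKY factors (9 of 18 lower, median -1.13, adjusted p = 7.7e-04), oxidative stress (7 of 15 lower and 1 higher, median -1.28, adjusted p = 0.026), immunity (5 of 14 lower, median -0.62, adjusted p = 0.026) and glucosinolates (6 of 13 lower and 1 higher, median -0.39, adjusted p = 0.017). The counts were 23, 20, 16, 11, 7, 8 and 6 within the list, and these had adjusted p = 0.62 by estimated correlation. AOC1 (-1.73), JAZ2 (-1.04) and the glucosinolate gene MAM3 (-2.84) were among these. Lists higher in Col-0 were photosynthesis (6 of 32 higher, median 0.29, adjusted p = 5.1e-04), phenylpropanoids (5 of 14 higher, median 0.52, adjusted p = 0.017) and auxin (6 of 16 higher, median 0.63, adjusted p = 0.017), with the flavonoid gene F3'H at 1.71 and EXPA1 at 1.49. The counts were 6, 7 and 7 within the list, and these had adjusted p = 0.62 by estimated correlation. Fry did not call photosynthesis (adjusted p = 0.096). In this pair 5418 genes passed, 2405 higher and 3013 lower in Col-0 than in C24, 8365 with a block within each treatment. Here 44.4% of calls were higher, and 33.5% with library totals alone.

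The comparison of CT101 with Te controls asked where these lines part without ozone. CSA1 averaged 69.6 ± 3.65 CPM in CT101 and 0.0673 ± 0.0781 CPM in Te (SD, n = 3; log2 fold change 9.88 ± 0.26), AT4G29200 was at least 1662-fold and AT5G15360 at least 659.9-fold higher in CT101. The Te to CT101 ratio was 2611 (95% interval 469 to 103142) for AT3G61010 and 1511 (95% interval 418 to 12477) for AT5G49440. FLC was lower in CT101 (-0.75 ± 0.12, adjusted p = 2.8e-04), and the other genes named in advance, PR1, PR2, PR5, ICS1, WRKY70, RBOHD, SLAC1 and ZAT12, did not pass. SLAC1 passed in DESeq2 (0.048), with the replicate block (0.015), in a separate fit (0.0498) and with a block within each treatment (0.01) (range 0.01 to 0.33). Lists that passed upward were salicylic acid (1 of 30 higher, median 0.39, adjusted p = 0.019), jasmonate (0 of 30 called, 6 at unadjusted p < 0.05, 0 in DESeq2, median 0.46, adjusted p = 0.019), glucosinolates (2 of 13 higher and 1 lower, median 0.28, adjusted p = 0.015), oxidative stress (1 of 15 higher, median 0.68, adjusted p = 0.026) and flower markers (1 of 2 higher, median 2.36, adjusted p = 0.019), the last through SEP1 (3.62), a floral identity gene that overlaps AT5G15790 on the other strand. The counts were 2, 0, 4, 1 and 2 within the list, and these had adjusted p = 0.58 to 0.72 by estimated correlation. Lists that passed downward were auxin (2 of 16 lower, median -0.37, adjusted p = 0.015) and photosynthesis (0 of 32 called, 2 at unadjusted p < 0.05, 0 in DESeq2, median -0.13, adjusted p = 0.029), with SAUR15 at -1.41. The counts were 3 and 0 within the list, and these had adjusted p = 0.72 to 0.83 by estimated correlation. Of these 7 lists fry called the flower markers and not the others (adjusted p = 0.2 to 0.62). In this comparison 1075 genes passed, 596 higher and 479 lower in CT101 than in Te, and 2171 passed with a block within each treatment.

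Whether genes that ozone changes already differ between lines without ozone was asked with the genes called in Col-0, which share no library with the lines compared. The 6169 genes that ozone raised in Col-0, ICS1, RBOHD and WRKY40 among them, had a median log2 difference of -0.29 between Te and C24 controls, where the median of all genes was -0.05. Of these genes 1956 (31.7%) were lower and 246 (3.99%) higher in Te, and camera gave p = 1.1e-12, or p = 0.16 by estimated correlation. The mean score of the set per library was -0.31 ± 0.06 in Te and 0.60 ± 0.14 in C24 (SD, n = 3), with a 2-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries can give. Between CT101 and C24 controls the median was -0.22, with 1209 lower and 144 higher (camera p = 1.5e-12, or p = 0.17 by estimated correlation). The 5527 genes that ozone lowered in Col-0, such as EXPA8 and BAS1, had medians of 0.17 in Te and 0.13 in CT101 relative to C24 (camera p = 7.8e-10 and 9.9e-10, or p = 0.22 and 0.22 by estimated correlation). Both differences rest on the same C24 control libraries.

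Whether Te and C24 responded to ozone differently was tested as the difference between their responses, over 12 libraries. AT1G57650, annotated as an ATP-binding protein, went from 0.219 to 184 ± 37.3 CPM in Te and from 1.28 to 3.06 ± 1.13 CPM in C24 (mean ± SD, n = 3), a difference in log2 fold change of 8.42 ± 0.93 (SE, adjusted p = 2.4e-05). DIN11 (AT3G49620) went from 0.406 to 259 ± 118 CPM in Te and from 1.9 to 6.23 ± 5.81 CPM in C24 (7.54 ± 1.16, adjusted p = 4.4e-04). The sucrose transporter gene SUC7 had no count in Te controls and 5.12 ± 1.65 CPM under ozone, against 0.528 and 1.68 CPM in C24. AT4G30230 (-2.77), AT1G29500 (-2.66) and AT3G47380, a pectin methylesterase inhibitor gene (-2.60), had lower responses in Te. ZAT12 rose more in Te (2.64 ± 0.65, adjusted p = 0.014). ZAT12 failed without C24 control replicate 2 (0.052) (range 2.6e-04 to 0.052). ICS1 (1.39 ± 0.46, adjusted p = 0.061), WRKY70 (1.08, 0.064), PR5 (1.90, 0.1) and RBOHD (0.72, 0.11) did not pass, nor did PR1, PR2, SLAC1 or FLC. ICS1 passed in DESeq2 (0.027), with the replicate block (0.044), with a block within each treatment (0.0059) and without C24 ozone replicate 3 (0.011) (range 0.0059 to 0.18). WRKY70 passed in DESeq2 (0.035), without C24 control replicate 3 (0.024) and without C24 ozone replicate 1 (0.048) (range 0.024 to 0.22). PR5 passed with the replicate block (0.047) and in a separate fit (0.0036) (range 0.0036 to 0.25). RBOHD passed with a block within each treatment (0.032) (range 0.032 to 0.29). Lists with a higher response in Te were oxidative stress (10 of 15 higher, median 2.43, adjusted p = 1.5e-09), salicylic acid (11 of 30 higher, median 1.26, adjusted p = 4.1e-07), WRKY factors (7 of 18 higher, median 1.68, adjusted p = 5.0e-07), receptor-like kinases (10 of 31 higher and 1 lower, median 1.28, adjusted p = 2.3e-06), jasmonate (9 of 30 higher, median 1.43, adjusted p = 3.0e-06), immunity (5 of 14 higher, median 1.3, adjusted p = 8.3e-05), ethylene (6 of 23 higher, median 0.89, adjusted p = 1.7e-04), tryptophan (5 of 11 higher, median 0.83, adjusted p = 0.0011), transferases (5 of 12 higher, median 0.77, adjusted p = 0.0056) and senescence (2 of 6 higher, median 1.08, adjusted p = 0.011). The counts were 14, 18, 11, 16, 16, 6, 8, 7, 5 and 4 within the list, and these had adjusted p = 0.22 to 0.46 by estimated correlation. ZAT7 (4.31), CBP60G (3.28), EDS5, a transporter for salicylic acid synthesis (3.24), WRKY25 (2.63), CRK36 (3.19), the defensin gene PDF1.2 (4.74), JAZ10 (2.73), MKK9 (1.73) and CYP71A12 (3.47) were among them. Lists with a lower response were auxin (3 of 16 lower, median -1.10, adjusted p = 2.9e-05) and photosynthesis (0 of 32 called, 1 at unadjusted p < 0.05, 0 in DESeq2, median -0.30, adjusted p = 1.7e-04), with PIN7 at -1.25. The counts were 7 and 0 within the list, and these had adjusted p = 0.22 to 0.61 by estimated correlation. Fry did not call transferases and photosynthesis (adjusted p = 0.052 to 0.28). In all 1970 genes differed (1598 higher and 372 lower in Te), 1548 of which rose more in Te and 39 went opposite ways. The number was 3041 with the replicate block, 4817 with a block within each treatment (3095 higher), 1248 without C24 control replicate 2 and 1227 without Te ozone replicate 3.

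The response of CT101 was set against that of C24 in the same way. DIN11 went from 0.338 to 219.6 ± 102 CPM in CT101 and from 1.9 to 6.23 ± 5.81 CPM in C24 (SD, n = 3; difference 7.58 ± 1.17, adjusted p = 9.1e-04), and AT1G57650 differed by 6.49 ± 0.81, RAP2.6, an ERF transcription factor gene, by 5.36 ± 1.11 and AT1G59950 by 5.73 ± 1.18. XTH31, a cell wall xyloglucan enzyme gene, had a lower response in CT101 (-2.61 ± 0.52). ZAT12 (2.00, adjusted p = 0.048) and WRKY70 (1.23, adjusted p = 0.036) rose more in CT101. ZAT12 failed without C24 control replicate 1 (0.057), 2 (0.15) or 3 (0.056), C24 ozone replicate 1 (0.064) or 2 (0.1), CT101 control replicate 1 (0.082), 2 (0.072) or 3 (0.1), CT101 ozone replicate 1 (0.054) or 3 (0.15), with no filter (0.081), in a separate fit (0.11) (range 0.0012 to 0.15). WRKY70 failed without C24 control replicate 2 (0.13), C24 ozone replicate 2 (0.1), CT101 control replicate 1 (0.098) or 2 (0.069), CT101 ozone replicate 1 (0.062) or 3 (0.082), in a separate fit (0.096) (range 0.01 to 0.13). ICS1 (1.01, adjusted p = 0.16), RBOHD, PR1, PR2, PR5, SLAC1 and FLC did not pass. ICS1 passed with a block within each treatment (0.026) and without C24 ozone replicate 3 (0.035) (range 0.026 to 0.36). Lists with a lower response in CT101 were photosynthesis (7 of 32 lower, median -0.70, adjusted p = 1.5e-12), glucosinolates (1 of 13 lower, median -0.35, adjusted p = 0.015) and auxin (0 of 16 called, 8 at unadjusted p < 0.05, 4 in DESeq2, median -0.80, adjusted p = 0.019). The counts were 30, 0 and 2 within the list, and these had adjusted p = 0.35 to 0.54 by estimated correlation. Higher in CT101 were oxidative stress (7 of 15 higher, median 2.00, adjusted p = 4.1e-07), salicylic acid (9 of 30 higher, median 1.12, adjusted p = 8.6e-06), WRKY factors (6 of 18 higher, median 1.49, adjusted p = 1.8e-05), transferases (2 of 12 higher, median 1.96, adjusted p = 3.4e-04), immunity (3 of 14 higher, median 0.79, adjusted p = 3.8e-04), jasmonate (5 of 30 higher, median 0.98, adjusted p = 4.3e-04), receptor-like kinases (7 of 31 higher and 1 lower, median 0.73, adjusted p = 4.3e-04) and ethylene (3 of 23 higher, median 0.56, adjusted p = 0.0024). The counts were 12, 14, 10, 5, 6, 8, 10 and 7 within the list, and these had adjusted p = 0.35 by estimated correlation. ZAT7 (3.68), EDS5 (3.01), WRKY46 (2.43), PDF1.2 (4.57), CRK13 (3.28) and ACO4 (1.46) were among these. Fry did not call glucosinolates and auxin (adjusted p = 0.093 to 0.19). In this pair 1995 genes differed (1458 higher and 537 lower in CT101), 3914 with the replicate block, 6011 with a block within each treatment (3336 higher) and 684 in a fit of the 12 libraries alone. Leaving out single libraries gave 816 without CT101 ozone replicate 3 to 3097 without C24 ozone replicate 3.

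Whether Col-0 responded differently from C24 was tested next. The jasmonate synthesis genes AOC1 (2.9 ± 0.37, difference in log2 fold change ± SE), AOC2 (2.32 ± 0.28) and OPCL1 (1.52) rose more in Col-0. NATA1, an N-acetyltransferase gene of ornithine metabolism, went from 0.656 to 28.8 ± 16.5 CPM in Col-0 and from 17.37 to 10.5 ± 4.15 CPM in C24 (SD, n = 3; 6.11 ± 0.93), and DIN11 differed by 7.64 ± 1.15. Responses were higher in C24 for WRKY41 (-3.69 ± 0.60), AT3G47380 (-2.68) and the receptor kinase gene AT3G45390 (-2.63). None of PR1, PR2, PR5, ICS1, WRKY70, RBOHD, SLAC1, ZAT12 and FLC passed, with ZAT12 at 2.04 (adjusted p = 0.096). ZAT12 passed in DESeq2 (0.024), with a block within each treatment (0.0033) and without C24 ozone replicate 3 (0.047) (range 0.0033 to 0.29). Lists with a higher response in Col-0 were jasmonate (7 of 30 higher, median 1.53, adjusted p = 7.5e-13), oxidative stress (1 of 15 higher, median 1.27, adjusted p = 1.2e-05), WRKY factors (2 of 18 higher, median 1.15, adjusted p = 7.2e-05), receptor-like kinases (2 of 31 higher, median 0.43, adjusted p = 0.0027), immunity (1 of 14 higher, median 0.63, adjusted p = 0.0082), reactive oxygen scavenging (3 of 14 higher, median 0.28, adjusted p = 0.012), ethylene (2 of 23 higher, median 0.39, adjusted p = 0.017) and tryptophan (3 of 11 higher, median 1.04, adjusted p = 0.017). The counts were 19, 4, 7, 4, 3, 3, 2 and 5 within the list, and these had adjusted p = 0.17 to 0.63 by estimated correlation. The glutathione synthetase gene GSH2 was at 2.48. Those with a lower response were auxin (1 of 16 lower, median -0.99, adjusted p = 1.5e-08) and photosynthesis (0 of 32 called, 0 at unadjusted p < 0.05, 0 in DESeq2, median -0.13, adjusted p = 0.016), and the salicylic acid list did not pass (adjusted p = 0.094). The counts were 8 and 0 within the list, and these had adjusted p = 0.13 to 0.7 by estimated correlation. Of these 10 lists fry called jasmonate, reactive oxygen scavenging and auxin and not the others (adjusted p = 0.056 to 0.64). Here 692 genes differed (588 higher and 104 lower in Col-0), 1156 with the replicate block, 2516 with a block within each treatment (1788 higher) and 384 in a fit of the 12 libraries alone. Single libraries left out gave 369 without Col-0 control replicate 3 to 976 without Col-0 ozone replicate 2.

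Between CT101 and Te the responses differed in few genes. SUS1 (AT5G20830), a sucrose synthase gene, went from 45.8 to 366 ± 68.5 CPM in CT101 and from 61.6 to 86.7 ± 16 CPM in Te (SD, n = 3; 2.51 ± 0.34, adjusted p = 6.2e-04). The calmodulin-like gene CML38 rose less in CT101 (-3.53 ± 0.57), APPR6 had a lower response there (-2.61), and the kinase genes AT5G41730 (6.07 ± 0.94) and AT5G50330 (2.29 ± 0.24) and NAC003 (2.35) were higher in CT101. None of the genes named in advance passed, and PR5 had the value -1.69 (adjusted p = 0.74). Lists with a lower response in CT101 were photosynthesis (0 of 32 called, 6 at unadjusted p < 0.05, 0 in DESeq2, median -0.41, adjusted p = 2.3e-09), glucosinolates (0 of 13 called, 0 at unadjusted p < 0.05, 0 in DESeq2, median -0.37, adjusted p = 5.1e-04) and tryptophan (0 of 11 called, 1 at unadjusted p < 0.05, 0 in DESeq2, median -0.43, adjusted p = 0.031). The counts were 0, 0 and 0 within the list, and these had adjusted p = 0.72 by estimated correlation. The list with a higher response was auxin (0 of 16 called, 2 at unadjusted p < 0.05, 0 in DESeq2, median 0.39, adjusted p = 0.0074). The count within the list was 0, and the list had adjusted p = 0.72 by estimated correlation. Fry called none of the 4 (adjusted p = 0.64 to 0.66). With the replicate block the tryptophan list had an adjusted p of 0.0672. In all 66 genes differed (32 higher and 34 lower in CT101), and 1200 had an unadjusted p under 0.05. The total was 115 in DESeq2, 120 with the replicate block, 330 with a block within each treatment (115 higher) and 41 in a fit of the 12 libraries alone. Leave-one-out totals were 27 without Te control replicate 2 to 53 without CT101 ozone replicate 2.

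Where along the chromosomes CT101 differs from C24 was asked by counting neighbouring tested genes that were both called between their controls. There were 869 such pairs, against 565 on average with permuted calls. The ratio was 1.54 (1-sided permutation p = 0.0001, the smallest 10000 permutations give), or 2.36 for calls of at least 2-fold. Te and C24 controls gave 1.15 (2-fold 1.64), Col-0 and C24 1.22 (1.83), CT101 and Te 2.87 (4.24) and ozone in C24 1.04. The share called caps ratios, so these are not comparable. With 1 gene per 100 kb CT101 and C24 gave 1.23 (permutation p = 0.06). Of 1370 genes that differed between Te and C24 controls by at least 2 on the log2 scale, CT101 was nearer to Te in 1023 (74.7%), though neighbours are not independent. On chromosome 1 that share was 79.9%, on chromosome 2 182 of 202 genes, on chromosome 3 84% and on chromosome 4 83.1%, and on chromosome 5 it was 44.8%.

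**Figure D5:**
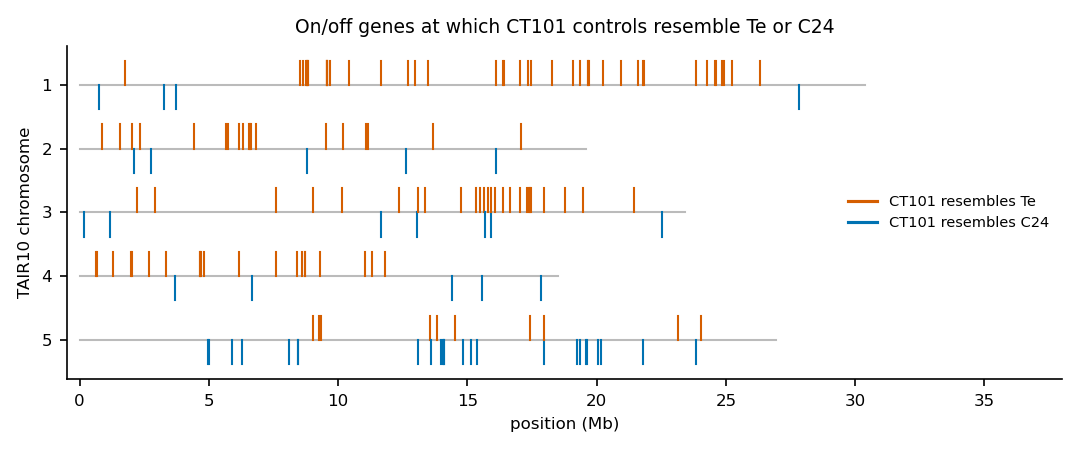
Genes that were on in the controls of either C24 or Te and off in the other, by position in Mb (horizontal) on each TAIR10 chromosome (vertical), coloured by whether CT101 controls resemble Te or C24. Chromosome 5 holds 25 genes like C24 and 10 like Te.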

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

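The splits and regroupings of libraries and the tests of explanations in this part were chosen only after the results were seen, while the comparisons and the fits of the compared libraries alone were chosen before. The differences in ozone response numbered 1970 genes between Te and C24, 1995 between CT101 and C24, 692 between Col-0 and C24 and 66 between CT101 and Te, each here because the test of the difference called genes. In a fit of the 12 libraries alone the counts were 1793, 684, 384 and 41, and among 25 regroupings drawn from the 200 possible the highest other counts were 524, 373, 326 and 31. Each of these kept the real lines in 1 treatment and so part of the difference. The regroupings that kept them in neither (21, 19, 20 and 20) called 0 genes, with at most 1704, 2218, 1406 and 3097 at an unadjusted p under 0.05. Only the real 1 of each 25 gave as many (share 0.04). Mixing lines widens the spread, so these counts cannot decide on chance.

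Between 3 and 3 libraries only 10 splits exist (1 as large in each), too few for a share under 0.05. In fits of the 6 libraries alone the ozone responses gave 7761 genes in C24, 12343 in Te, 12178 in CT101 and 10660 in Col-0. The control differences gave 6834 between Te and C24, 3332 between CT101 and C24, 5254 between Col-0 and C24 and 943 between CT101 and Te. The others gave 0, but they too mix groups.

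Salicylic acid genes were higher in C24 controls than in Te controls, in 28 of 30 members. A single library argues poorly for this, since at least 24 members stayed called whichever of the 6 libraries was left out (24 without C24 control replicate 2, 29 at most). The list was also lower in Col-0 than in C24 (median -1.20, quartiles -2.02 and -0.93). That test holds no Te library, so poorer alignment of Te reads remains open. Ozone that reached the C24 control plants during the treatment should raise no gene beyond what the full treatment does. This assumes that responses grow with dose and are alike in C24, Col-0 and Te. In C24 controls 6 of 30 members exceeded Te controls by more than the ozone response in Col-0, and exceeded ozone-treated Te. These were AED1, PR1, LURP1, PCC1, ACD6 and NIMIN3 (both tests adjusted over the list), of which only ACD6 had risen in Col-0. Leaving out 1 of the 15 libraries gave 4 to 6 such members, and AED1, LURP1, PCC1 and ACD6 held throughout. On these assumptions this argues against such an exposure for these 4. PR1 failed with 5 of these omissions and NIMIN3 with 8. For the 22 other members that differed, the control difference less the ozone response in Col-0 had a median of -0.66 with quartiles of -1.46 and 0.61, and a partial exposure cannot be told apart from a difference between the accessions, since none of these passed both tests with all libraries (WRKY38 did without Col-0 control replicate 1 or Col-0 ozone replicate 3). A lasting difference between the accessions may underlie the pattern and remains untested, as do an earlier exposure and differences in growth or infection between the plants.

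Te changed more than C24 under ozone. Over the 11696 genes called in Col-0 the median absolute log2 fold change was 0.644 in C24 and 1.02 in Te, a ratio of 1.58. Depth is argued against by a ratio of 1.59 with all libraries thinned to 13633768 counts, and a single library by a lowest ratio of 1.33, without C24 ozone replicate 2, and a highest of 1.82. Higher control levels in C24 with an equal level under ozone could not be excluded. The 3526 genes that rose at least 2-fold in Col-0 differed by 0.343 under ozone, but the pairs of equally numbered libraries gave 0.144, 0.667 (with C24 ozone replicate 2) and 0.215, a 95% interval of the mean of -0.36 to 1.05, and the control difference was -0.49, so this and a smaller response in C24 cannot be told apart.

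CT101 controls resembled C24 in some stretches of the chromosomes and Te in others. Of 165 genes on (over 2 CPM) in either C24 or Te and off (under 0.15 CPM) in the other, 119 resembled Te and 46 C24. The cut for CT101 lay between 24.9 (DMP1) and 26.2 percent (ELI3-2) of the on level. Between 10 and 50 percent lay 23 (13.9%) and under 10 lay 79, some on in C24 and some in Te. A C24 and Te mixture would keep 1 kind over 50, so the 79 argue against it. Copies or shared regulation of neighbours cannot be told apart from inherited stretches, since among 129 genes at least 100 kb apart there were 36 switches against 42.6 permuted within chromosomes (permutation p = 0.054) and 51.9 permuted over all (p = 8e-04). Descent of CT101 from a cross of C24 and Te is a candidate explanation, as 1 gene, AT3G61010, set CT101 apart from both where these were alike, against 76 for Col-0.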

How the results depend on the processing

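The library-total scaling, the block within each treatment and the spacing of 1 gene per 100 kb were chosen after seeing the data, and the other alternatives were chosen before the data were examined. Omitting the organelle loci, which held 0 counts, could change nothing. With RLE factors, no filter or library totals alone, all 12 counts of genes stayed within 1.5 times their value, with DESeq2 11 of 12, with the replicate block 8 and in fits of the compared libraries alone 9. Of 907 called genes that the naming rule gave, 702 (77.4%) held in all alternatives, 91.8% of those from ozone responses, 68.7% from control differences and 56.2% from response differences. The 284 genes printed were picked from these after their stability was seen, and 94% of them held, against 69.8% of the 623 not printed. For response differences the shares were 93.3% and 43.5%, so the printed genes do not represent the rest. Of the 907, 713 held whichever library was left out.

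The response difference of Te and C24 (1970) became 3041 with the replicate block and 4817 with a block within each treatment, a pairing the main fit omits. Between CT101 and C24 (1995) it became 3914, 6011 and, in a fit of the compared libraries alone, where fewer libraries estimate the spread, 684. Between Col-0 and C24 (692) the same settings gave 1156, 2516 and 384, and between CT101 and Te (66) they gave 120, 330 and 41, with 115 in DESeq2. The block within each treatment also raised the control differences CT101 minus C24 to 6284, Col-0 minus C24 to 8365 and CT101 minus Te to 2171. Apart from the smaller fit, the cause was not tested.

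Leaving out each library in turn gave ozone responses of 6982 to 10509 genes in C24, 11835 to 12455 in Te, 12486 to 13329 in CT101 and 10156 to 11648 in Col-0, and control differences of 4768 to 5561 for Te minus C24, 2184 to 3034 for CT101 minus C24 (lowest without CT101 control replicate 1), 4003 to 4949 for Col-0 minus C24 and 746 to 917 for CT101 minus Te. Response differences ran from 1227 to 2334 for Te minus C24, where 1248 without C24 control replicate 2 and 1227 without Te ozone replicate 3 moved the count by over 1.5 times. For CT101 minus C24 the range was 816 to 3097, with 906 without C24 control replicate 2, 1025 and 3097 without C24 ozone replicate 2 or 3, 997 without CT101 control replicate 1 and 1192, 2998 and 816 without CT101 ozone replicate 1 or 2 or 3. For Col-0 minus C24 it was 369 to 976, with 441 and 382 without C24 control replicate 1 or 2, 397 and 369 without Col-0 control replicate 1 or 3 and 373 and 420 without Col-0 ozone replicate 1 or 3. For CT101 minus Te it was 27 to 53, with 28, 27 and 31 without Te control replicate 1 or 2 or 3, 37 and 36 without Te ozone replicate 1 or 3, 38, 43 and 33 without CT101 control replicate 1 or 2 or 3 and 39 and 36 without CT101 ozone replicate 1 or 3. For each the cause was not tested.

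Of 123 list calls 3 held with an estimated correlation, 97 with fry, which lost none in the ozone responses, and 121 with the replicate block, which added 6. Beyond the values printed with the results and here, the replicate block changed no call of a printed gene or list. Fry pointed the other way for guard cells in ozone-treated Te (adjusted p = 0.0157, range 0.0157 to 0.984 over the alternatives) and for flowering time between Col-0 and C24 controls (adjusted p = 0.0153, range 0.0153 to 0.853). It tests the members' own direction and does not compare the list with other genes. Senescence passed with the replicate block in ozone-treated CT101 (adjusted p = 0.0409) and Col-0 (0.0364), and the receptor-like kinases did between CT101 and Te controls (0.0424). Requiring a 2-fold change in both lines lowered the shared calls to 3332 for C24 and Te, 3440 for C24 and CT101, 3190 for C24 and Col-0, 5695 for Te and CT101, 4680 for Te and Col-0 and 4665 for CT101 and Col-0, since fewer genes meet it. With an estimated correlation the genes raised in Col-0 had p = 0.164 between Te and C24 controls and 0.166 between CT101 and C24 controls, and the lowered genes 0.222 and 0.225. The neighbour ratio of CT101 was 1.23 with 1 gene per 100 kb, where fewer genes were tested.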

Other observations

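The tests of stretches in this part were chosen only after the results were seen, and the gene lists were fixed in advance. Values of lists run in the order C24, Te, CT101, Col-0. Of 12 measured circadian clock genes, 3, 4, 5 and 2 rose and 4, 4, 6 and 3 fell. Median log2 changes were -0.22, -0.24, -0.39 and -0.15. Of 6 measured senescence genes, 2, 5, 5 and 5 rose and 0, 0, 0 and 0 fell. Their medians were (log2) 1.21, 2.26, 1.68 and 1.55. Of 10 measured flowering time genes, 0, 0, 0 and 0 rose and 1, 2, 2 and 1 fell. The medians (log2) were -0.13, -0.32, -0.23 and -0.15. The senescence list passed in Te (adjusted p = 0.024, and adjusted p = 0.21 with an estimated correlation), with 4, 5, 5 and 5 members higher adjusted over the list alone, and the clock and flowering lists passed in no line. LUX, a component of the evening complex of the clock, rose in C24 (1.2), Te (3.48), CT101 (3.5) and Col-0 (2.11), and the morning gene CCA1 fell in Te (-1.41). SAG13 rose in Te by 5.76, and the flowering repressor SVP fell in C24 (-0.89) and Col-0 (-1.26). Between controls, MAF1, a relative of FLC, was higher in Te (5.11) and Col-0 (4.80) than in C24 and MAF4 was lower (-5.12 and -2.11), and CT101 differed from Te by -5.30 in MAF1 and 4.66 in MAF4. Of the root markers 1 gene was measured and of the flower markers 2, and neither list passed under ozone, with AG lower in CT101 (-2.59) and Col-0 (-1.87).

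A hypothesis was that CT101 and Te part where CT101 carries stretches like those of C24. Of 65 genes whose responses differed, outside those that defined the stretches, 34 (52.3%) lay in C24-like stretches and 5 in Te-like ones, against 23.8% of all tested genes in C24-like stretches (odds ratio 3.53, Fisher's exact p = 6.3e-07). Of 1029 genes that differed between the controls, 414 (40.2%) lay there (odds ratio 2.26, Fisher's exact p = 2.8e-33). Both go with the hypothesis, though genes of a stretch are not independent, and the same libraries defined the stretches. Some genes that defined them, such as ARI12, also respond to ozone.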
